A study of Homo sapiens with 4 samples.

How the data were processed

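RNA from HCT116 cells was sequenced in 4 libraries, 2 titled as control siRNA and 2 as siRNA against ONECUT2. Per the labels' protocols, mRNA was purified with poly-T beads, fragmented, primed with random hexamers and made into libraries with the NEBNext Ultra kit, and over 6G of raw data were generated per sample. Poly(A) selection leaves RNAs without a poly(A) tail, such as most histone mRNAs, tRNAs and small nucleolar RNAs, poorly measured. The authors deposited 1 table of TPM per gene symbol with a column per library, named as salmon abundance. The genome build was hg38, per the submitters' processing notes. The version of salmon, its index, the gene annotation, any read filter and the strand setting are not given in the sources used here. TPM divides by transcript length and scales each library to a fixed total, so that a rise in abundant transcripts lowers all others, and depth is not kept.

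The deposited TPM table held 55375 symbols, of which 54686 are in GENCODE release 29 (GRCh38), which was used for gene identifiers, coordinates, types and 3' UTRs. Of these symbols, 24264 were above 0 in at least 1 library. The columns summed to 98.2% of the TPM scale in each library (982382, 982200, 981793 and 982207 TPM), and the rest is not analysed here. The 10 most abundant symbols held 17.1%, 15.3%, 16.0% and 16.5% of the total, led by MT-ND4L in each library, and protein-coding genes held 97.3%, 97.3%, 96.7% and 96.8%. No pair of libraries shared an equal value above 0 in any gene. All sample columns were used. Since TPM keeps no counts, depths, counting intervals and detection limits are unknown, and precision is given by the spread between the libraries of a group.

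Libraries were grouped by their titles and treatment labels. Genes with a mean of at least 1 TPM over the 4 libraries were tested on log2(TPM + 1), that is with a pseudocount of 1 TPM and no rescaling, in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with a variance trend, two-sided). The fit had 2 residual degrees of freedom per gene, with a median of 3.64 added by moderation. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Fold changes are siONECUT2 minus siControl on the log2(TPM + 1) scale, and means ± SD are of TPM over 2 libraries per group unless stated otherwise. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

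The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named ONECUT2 and TRMT61A. It also named the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, a mean of at least 5 TPM, a symbol and both siONECUT2 libraries on the same side of both controls. From each list it took up to 4 members with the smallest p, together with DUSP6, SPRY4, ETV4, ETV5, FOSL1, MAPK3, MAP2K1, MAP2K2 and BRAF, and ONECUT1 and ONECUT3 as values. Some genes that the rule names are not reported here. The 25 lists held 675 names, of which 671 matched the table, 28 of them by an older symbol. RPS6KA1, TGFB1 and H2BC5 were not analysed here, and RIGI is the newer name of DDX58, which was already listed. Lists with at least 5 tested genes were tested with camera at a preset correlation between genes of 0.01. They were also tested with camera at an estimated correlation and with fry, and p-values were adjusted over the 21 lists tested. At an estimated correlation camera uses only the 2 residual degrees of freedom, which limits how low its p-values can go.

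The alternatives were pseudocounts of 0.1 and 0.5 TPM, no expression filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization and rescaling without mitochondrial genes. Others were the replicate number as a block, eBayes without a trend or with robust moderation, a threshold of 0.01, a minimum of 2-fold, and leaving out each library in turn. In the latter the lone library of a group is assumed to vary like the other group. A correction for GC content and transcript length was added after seeing the data, for 11654 tested genes with an annotated 3' UTR (86.4% of tested and 94.6% of called genes). Across genes, the Spearman correlation of the log2 fold change was 0.165 with GC content and 0.0654 with length.

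The fit was tested on simulated data drawn for the 13485 genes of this comparison, with 200 genes changed in each of 5 simulations. It recovered 52.7% of 1.5-fold, 83.1% of 2-fold and 95.2% of 4-fold changes, and 5.93% of calls were false. These folds were planted on the log2(TPM + 1) scale, where a low gene changes more in TPM, and the noise had the moderated variances. The 200 changed genes are also far fewer than the 25.5% of genes called in the data. The rates are therefore not those of the gene calls reported here. A planted list was called in 5 of 5 simulations and other lists in 0 of 100 tests. The noise was drawn independently for each gene, whereas estimated correlations within the lists reached 0.796 in the data. The simulations therefore do not give the rate of false list calls in these data. For 11654 genes, 3' UTRs were searched for each 7-base word (heptamer) present in at least 100 genes. Genes with and without it were compared by a z score of the log2 fold change after adjustment for GC content, length and expression, and 200 random gene orders gave its range by chance. A heptamer planted in simulated data with a log2 effect of -0.15 ranked lowest in 5 of 5 simulations.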

Results

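RNA abundance was measured by poly(A) RNA sequencing in HCT116 cells, a human colon carcinoma line. The 4 libraries fell into 2 groups of 2. The control libraries (siControl 1 and 2) are titled as control siRNA and labelled as wild type for treatment, and the other libraries (siONECUT2 1 and 2) are labelled as treated with siRNA against ONECUT2, a homeodomain transcription factor. The series title concerns MAPK/ERK signalling and TRMT61A, the catalytic subunit of the tRNA m1A methyltransferase. The design text describes a TRMT61A knockout, which no sample label names. The libraries were therefore grouped by the sample labels, and both genes are reported in every library. The labels do not say whether the 2 libraries of a group came from separate cultures or from different siRNAs, so p-values measure only the spread between these samples, which may be technical. Values are TPM, a scale on which the transcripts of each library share a fixed total, which keep no read depth, so the depth behind each value is unknown. The 4 libraries listed 13412, 13559, 13660 and 13434 symbols at 1 TPM or more. Pearson's r of log2(TPM + 1) across tested genes was 0.987 between the control libraries, 0.986 between the siONECUT2 libraries and 0.968 to 0.969 between groups, across genes that are not independent replicates.

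ONECUT2 was listed at 1.52 and 1.77 TPM in the control libraries and at 0.625 and 0.587 TPM in the siONECUT2 libraries. The control mean of 1.64 ± 0.177 TPM was 2.71 times the siONECUT2 mean of 0.606 ± 0.0269 TPM (SD, n = 2 libraries per group). On the log2(TPM + 1) scale, which understates the change of low genes, the difference was -0.72 (SE 0.23, 95% interval -1.29 to -0.14), and its limma adjusted p = 0.0743 did not pass the threshold of 0.05. With pseudocounts of 0.5 and 0.1 TPM in place of 1 TPM, the difference was -0.95 and -1.30 (adjusted p = 0.0780 and 0.0890). It passed with variances moderated without a trend on expression (adjusted p = 0.0250) and after a correction for GC content and length chosen after seeing the data (log2 fold change -0.73, adjusted p = 0.0249). ONECUT2 (ENSG00000119547.5) lies on the plus strand of chromosome 18 at 57435685 to 57491297 in GRCh38. TRMT61A (ENSG00000166166.12, chromosome 14 at 103529184 to 103537073) was listed at 12.8 and 12.1 TPM in the control libraries and at 13.9 and 16 TPM in the siONECUT2 libraries. Its log2 fold change was 0.24 (SE 0.11, limma adjusted p = 0.170), and both siONECUT2 libraries lay above both controls. It was 0.15 without siONECUT2 2 and also after the GC and length correction (adjusted p = 0.480 and 0.395). Of the paralogs, ONECUT1 was at 0.438 and 0.572 TPM in controls and 0.583 and 0.438 TPM in siONECUT2 libraries, and ONECUT3 was at 7.99 and 8.04 TPM against 11.4 and 9.27 TPM.

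**Figure D1:**
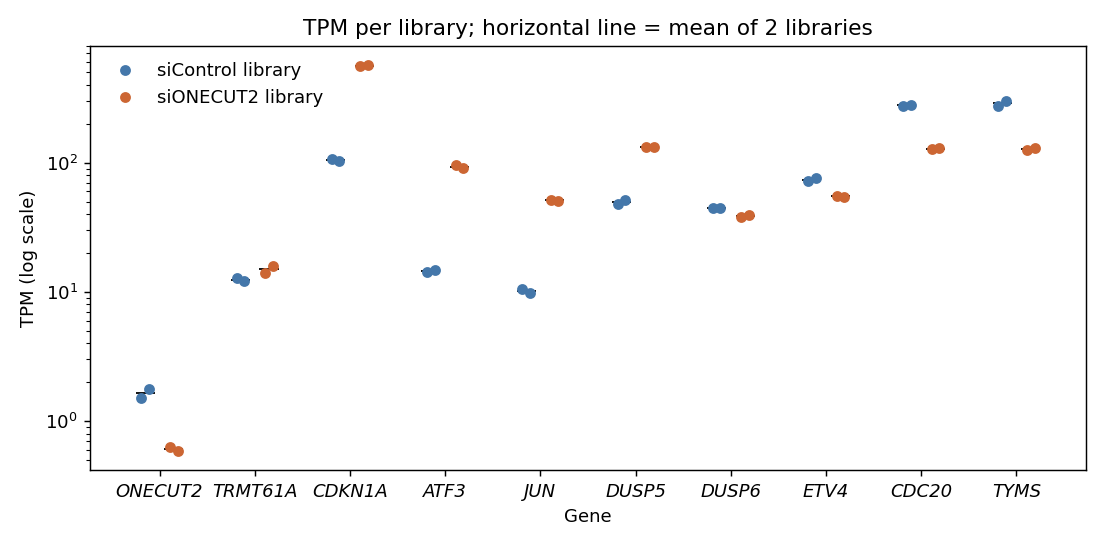
TPM on a log scale in each of the 4 libraries for 10 genes, with siControl libraries in blue, siONECUT2 libraries in orange and a horizontal line at the mean of the 2 libraries of a group. ONECUT2 lies at 1.52 and 1.77 TPM in controls and at 0.625 and 0.587 TPM in siONECUT2 libraries, while CDKN1A lies at 106 TPM on average in controls and at 564 TPM in siONECUT2 libraries.

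The comparison of siONECUT2 with siControl asks which RNAs differ when ONECUT2 is targeted. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 106 ± 2.66 to 564 ± 5.77 TPM (log2 fold change 2.40, SE 0.05, adjusted p = 0.000111). ATF3, a stress-induced transcription factor, rose from 14.6 ± 0.365 to 93.2 ± 2.94 TPM, and JUN, a subunit of AP-1, rose from 10.2 ± 0.513 to 51.2 ± 0.711 TPM. SESN2, a sestrin induced by p53 and by ATF4, rose from 5.58 ± 0.0606 to 30.2 ± 0.419 TPM. TSC22D3, known as a glucocorticoid-induced gene, rose from 4.88 ± 0.337 to 22.4 ± 0.407 TPM, and ANGPTL4, a secreted inhibitor of lipoprotein lipase whose locus overlaps RAB11B-AS1, from 5.10 ± 0.173 to 24.9 ± 6.20 TPM. The log2 fold changes of these 6 genes lay between 1.99 and 2.60, with adjusted p from 0.000111 to 0.00209.

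Among the 10 largest falls, GTF3C6, a subunit of the RNA polymerase III factor TFIIIC, went from 73.2 ± 3.94 to 17.3 ± 0.534 TPM (log2 fold change -2.02, SE 0.08, adjusted p = 0.000468). PLRG1, a spliceosome component, fell from 113 ± 14.3 to 30.2 ± 0.824 TPM, and RIDA, which hydrolyses reactive imines, from 53.1 ± 5.36 to 13.5 ± 0.683 TPM. IFT22, an intraflagellar transport gene, fell from 29.2 ± 0.276 to 7.85 ± 0.179 TPM, TRIM27 from 21.1 ± 3.43 to 2.39 ± 1.38 TPM, and KLHL5 from 15.1 ± 1.03 to 3.63 ± 0.259 TPM. Over all 10 falls the log2 fold change ran from -3.28 to -1.77 and the adjusted p from 0.000468 to 0.00633. HIBCH, an enzyme of valine breakdown, fell from 22.9 ± 1.47 to 4.79 ± 1.36 TPM and CISD3, a mitochondrial iron-sulfur protein gene, from 22.6 ± 2.0 to 5.94 ± 1.93 TPM. Both overlap other expressed genes (C2orf88 and INPP1 for HIBCH, PCGF2 for CISD3), so that their levels are uncertain. SNORD17, a small nucleolar RNA inside SNX5, was at 20.5 ± 3.03 and 4.83 ± 2.10 TPM, and its call was lost without siControl 2 (adjusted p = 0.0633).

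SMIM11A (chromosome 21 at 34375480 to 34407866) fell from 26.3 ± 3.56 to 1.81 ± 0.457 TPM. Its near-identical copy SMIM11B (chromosome 21 at 7744962 to 7777853) was listed at 0 in both controls and at 31.0 and 24.9 TPM in the siONECUT2 libraries. Their sum was 26.3 ± 3.56 TPM in controls and 29.8 ± 4.81 TPM in siONECUT2 libraries, so the split between the copies is uncertain. MT-TE, a mitochondrial tRNA, and AC009412.1 were also listed at 0 in both controls, and at 14.6 and 8.54 TPM and at 13.4 and 8.61 TPM in siONECUT2 libraries 1 and 2. No fold is given for genes listed at 0.

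Of 13485 genes tested, 1610 were higher and 1830 lower in the siONECUT2 libraries (limma with moderated variances, two-sided, adjusted p under 0.05), or 25.5% of those tested. At least 2-fold changes were called for 190 genes upward and 178 downward, and 5283 genes had an unadjusted p under 0.05. The siONECUT2 libraries lay on the same side of both controls in 65.7% of tested genes, where chance gives 33.3%, and in all 3440 called genes. For the called genes this largely follows from the call itself. Genes of the same 4 libraries are not independent, so the 65.7% is no test of the siRNA. An exact permutation test of 2 against 2 libraries cannot go below 0.333. The counts were 523 and 778 without siControl 1, 519 and 574 without siControl 2, 477 and 784 without siONECUT2 1, and 625 and 795 without siONECUT2 2. They were 749 and 968 without the expression filter and 1044 and 1186 without the variance trend. ETV4, ETV5, SPRY4, MAP2K1, BRAF, ELF3, DKK1, TPI1, ATP5F1A and ENG, named in what follows, share their span with another expressed gene. No source used here states a strand setting, so that the levels of these genes are uncertain. For all overlaps given here, whole gene spans with introns were compared. Shared exons were not looked for, so whether an overlap touches a level is unknown.

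**Figure D2:**
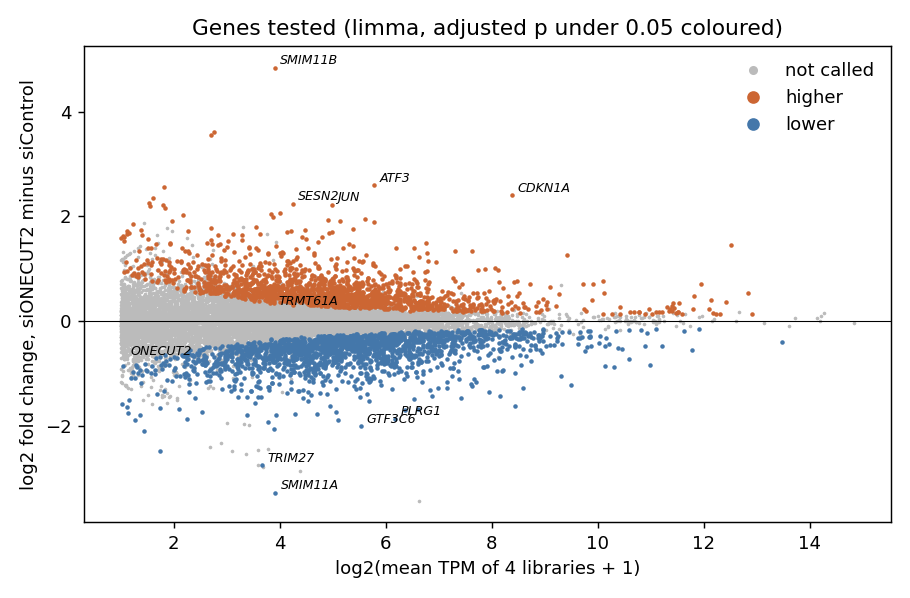
Log2 fold change of siONECUT2 minus siControl on the log2(TPM + 1) scale against log2 of the mean TPM plus 1, for the 13485 genes tested; each point is a gene, and orange and blue points are the 1610 higher and 1830 lower genes with adjusted p under 0.05. CDKN1A stands at a log2 fold change of 2.40, TRIM27 at -2.76, and ONECUT2 at -0.72 is not coloured.

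The series title names MAPK/ERK signalling, so transcripts that ERK activity is known to drive were set out as a list before the data were examined. JUN rose as above, DUSP5, a nuclear ERK phosphatase, rose from 49.8 ± 2.37 to 133 ± 0.253 TPM, and DUSP4, another, from 27.1 ± 1.29 to 61.6 ± 3.56 TPM. HMGA2, a chromatin protein gene whose locus overlaps RPSAP52, rose from 110 ± 2.63 to 196 ± 0.819 TPM. Of 39 members tested, 21 rose and 2 fell (24 and 5 adjusted over the list alone). Their median log2 fold change was 0.37. The list stood above other genes by camera at the preset correlation (adjusted p = 7.19e-06). With an estimated correlation camera did not call it (adjusted p = 0.212). That estimate was -0.0148, under the preset 0.01, so a stronger correlation between its genes did not remove the call. The feedback genes and ETS factors often used to read ERK output gave mixed values. DUSP6, the cytoplasmic ERK phosphatase, was at 44.4 ± 0.145 and 38.8 ± 0.771 TPM (log2 fold change -0.19, adjusted p = 0.0894). ETV5 was at 35.0 ± 0.328 and 34.0 ± 3.05 TPM (adjusted p = 0.731), and FOSL1 at 148 ± 8.81 and 127 ± 1.48 TPM (adjusted p = 0.0535). ETV4 fell from 74.0 ± 3.06 to 55.2 ± 0.780 TPM (log2 fold change -0.42, adjusted p = 0.00881), and SPRY4, a feedback inhibitor of the pathway, rose from 47.8 ± 4.13 to 61.6 ± 4.69 TPM (0.36, adjusted p = 0.0394). The ETV4 call was lost without siControl 2, siONECUT2 1 or siONECUT2 2 (adjusted p = 0.0645, 0.0545 and 0.0568). The SPRY4 call was lost without any 1 of the 4 libraries (adjusted p from 0.0721 to 0.169), without the expression filter (0.117) or without the variance trend (0.10). FOSL1 passed as lower with a mean of at least 5 TPM, with robust moderation and after the GC and length correction (adjusted p = 0.0384, 0.0496 and 0.0272).

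Among 42 tested genes of the RAS-RAF-MEK-ERK cascade itself, 4 rose and 2 fell (4 and 2 adjusted over the list alone), and camera gave adjusted p = 0.305 for the list (median log2 fold change 0.08). RPS6KA3, which encodes the ERK-activated kinase RSK2, fell from 21 ± 0.0783 to 8.57 ± 0.532 TPM, and RRAS, a RAS-related GTPase, rose from 29.2 ± 0.272 to 43.8 ± 0.189 TPM. KSR1, a scaffold of the cascade, was at 8.53 ± 0.961 and 16.4 ± 1.42 TPM (adjusted p = 0.00772), a call lost without siControl 1 or siONECUT2 1 (adjusted p = 0.0556 and 0.0614). The kinases MAPK3, MAP2K1, MAP2K2 and BRAF did not pass the test. MAPK3 was at 33.2 ± 4.55 and 32.6 ± 0.562 TPM, and MAP2K1 at 40.0 ± 0.173 and 36.9 ± 0.217 TPM. MAP2K2 was at 107 ± 2.89 and 121 ± 2.07 TPM (adjusted p = 0.0619), and BRAF at 6.60 ± 0.503 and 7.39 ± 0.201 TPM. MAP2K2 passed as higher with a mean of at least 5 TPM (adjusted p = 0.0481), with quantile normalization (0.0306) and when rescaled without mitochondrial genes (0.0486).

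Most genes listed as induced by p53 rose. Of 28 tested, 25 rose and none fell (25 and 0 adjusted over the list alone), with a median log2 fold change of 0.70 (camera adjusted p = 1.61e-15; adjusted p = 0.212 with an estimated correlation). Beside CDKN1A and SESN2, BBC3, which encodes the pro-apoptotic protein PUMA, rose from 13.7 ± 0.263 to 54.3 ± 1.70 TPM. The antiproliferative gene BTG2 rose from 17.9 ± 0.373 to 63.1 ± 2.15 TPM and GDF15, a secreted stress cytokine, from 111 ± 0.407 to 283 ± 12.0 TPM.

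Most proliferation genes listed fell. All 30 tested genes of G2/M and mitosis were lower (30 adjusted over the list alone; median log2 fold change -0.74, camera adjusted p = 2.21e-17; adjusted p = 0.212 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 278 ± 4.57 to 128 ± 1.72 TPM. TPX2, a spindle assembly factor, fell from 138 ± 4.41 to 68.1 ± 0.225 TPM, and BIRC5, which encodes survivin, from 148 ± 2.10 to 90.3 ± 0.883 TPM. Of 38 E2F targets and DNA replication genes, 32 fell and none rose (34 and 1 adjusted over the list alone; median log2 fold change -0.58, camera adjusted p = 1.56e-15; adjusted p = 0.216 with an estimated correlation). TYMS, thymidylate synthase, fell from 288 ± 16 to 127 ± 4.28 TPM and MCM6, a subunit of the replicative helicase, from 98.3 ± 3.28 to 52.0 ± 2.24 TPM. Overlapping genes (ENOSF1 and TYMSOS) make the level of TYMS uncertain.

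Many stress and inflammatory genes were higher. In the list of ATF4 targets and the unfolded protein response, 17 of 28 tested genes rose and none fell (19 and 2 adjusted over the list alone). Their median log2 fold change was 0.40 (camera adjusted p = 2.25e-07; adjusted p = 0.216 with an estimated correlation). DDIT3, which encodes the transcription factor CHOP, rose from 11.5 ± 1.25 to 46.8 ± 1.65 TPM and DNAJB9, an endoplasmic reticulum chaperone gene, from 9.55 ± 0.146 to 31.2 ± 1.01 TPM. Their loci overlap other expressed genes (MARS and MBD6 for DDIT3, PNPLA8 and THAP5 for DNAJB9), so that their levels are uncertain. ATF3 and SESN2 belong to this list too, and SESN2 also to that of p53 targets. Of 12 tested NF-kB and inflammatory genes, 10 rose and none fell (10 and 0 adjusted over the list alone; median log2 fold change 0.83, camera adjusted p = 3.13e-05; adjusted p = 0.216 with an estimated correlation). The chemokine gene CXCL8 rose from 0.312 ± 0.0351 to 4.85 ± 0.129 TPM, NFKBIA, an inhibitor of NF-kB, from 20.1 ± 0.664 to 35.6 ± 1.72 TPM. NFKB2, a subunit, rose from 22.6 ± 3.03 to 41.7 ± 0.297 TPM. The interferon response was not called as a list. Of its 22 tested genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.867), with a median log2 fold change of -0.08 and a mean of 0.01, which differ in sign.

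Genes of epithelial and of mesenchymal character were both higher on balance. Of 23 tested epithelial genes, 8 rose and 2 fell (11 and 2 adjusted over the list alone; median log2 fold change 0.13, camera adjusted p = 0.00654; adjusted p = 0.216 with an estimated correlation). The keratin gene KRT19 rose from 640 ± 20.4 to 1040 ± 21.2 TPM, KRT80, another, from 4.27 ± 0.178 to 17.2 ± 0.0548 TPM, and CLDN4, a tight junction claudin, from 73.8 ± 0.276 to 144 ± 2.31 TPM. Of 14 tested mesenchymal genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone; median log2 fold change 0.39, camera adjusted p = 0.00233; adjusted p = 0.283 with an estimated correlation). ITGA5, which encodes the fibronectin receptor subunit alpha-5, rose from 21.5 ± 2.77 to 43.5 ± 3.51 TPM. ACTA2, smooth muscle actin, rose from 4.80 ± 0.665 to 14.5 ± 1.13 TPM, although ACTA2 overlaps FAS, a p53 target. The member that fell was VIM, vimentin (5.26 ± 0.111 to 2.13 ± 0.131 TPM, log2 fold change -1.0, adjusted p = 0.010). Its call was lost without siControl 1, siControl 2 or siONECUT2 2 (adjusted p = 0.0675, 0.0769 and 0.0512) and without the expression filter (0.0535).

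Transcripts of the translation and respiration machinery showed smaller shifts. Of 50 cytosolic ribosomal protein genes, 19 rose and 1 fell (20 and 1 adjusted over the list alone; median log2 fold change 0.09, camera adjusted p = 3.38e-05; adjusted p = 0.216 with an estimated correlation). RPL12 rose from 3002 ± 92 to 4193 ± 48.0 TPM, and RPS19 was at 2606 ± 12.3 and 3309 ± 22.8 TPM (adjusted p = 0.00220, but 0.0521 without the variance trend). Of 40 nuclear-encoded oxidative phosphorylation genes, 13 fell and none rose (13 and 0 adjusted over the list alone). Their median log2 fold change was -0.12 (camera adjusted p = 0.00284; adjusted p = 0.282 with an estimated correlation). The list was not called with quantile normalization (adjusted p = 0.263) or after the GC and length correction (adjusted p = 0.10). NDUFB5, a complex I subunit gene, fell from 108 ± 0.318 to 64.5 ± 5.11 TPM and ATP5F1A, the ATP synthase alpha subunit gene, from 492 ± 17.6 to 360 ± 7.09 TPM. Of 13 mitochondrially encoded mRNAs, 3 were higher and 1 lower (3 and 1 adjusted over the list alone; median log2 fold change 0.06, camera adjusted p = 0.160). The list was called as higher without siControl 1 (adjusted p = 0.00127) or siONECUT2 1 (0.0334). Mitochondrial genes held 19.0% and 16.9% of the TPM total in the control libraries and 18.7% and 19.5% in the siONECUT2 libraries. MT-CO1 was the lower member, at 12960 ± 405 and 9831 ± 225 TPM (adjusted p = 0.00225). Its call was lost without the expression filter (0.0592) and with quantile normalization (0.282). Of 9 replication-dependent histone genes, 4 were higher and none lower (4 and 0 adjusted over the list alone; median log2 fold change 0.21, camera adjusted p = 0.0629). The list was called without siControl 1 (0.0143) or siONECUT2 1 (0.0334).

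**Figure D3:**
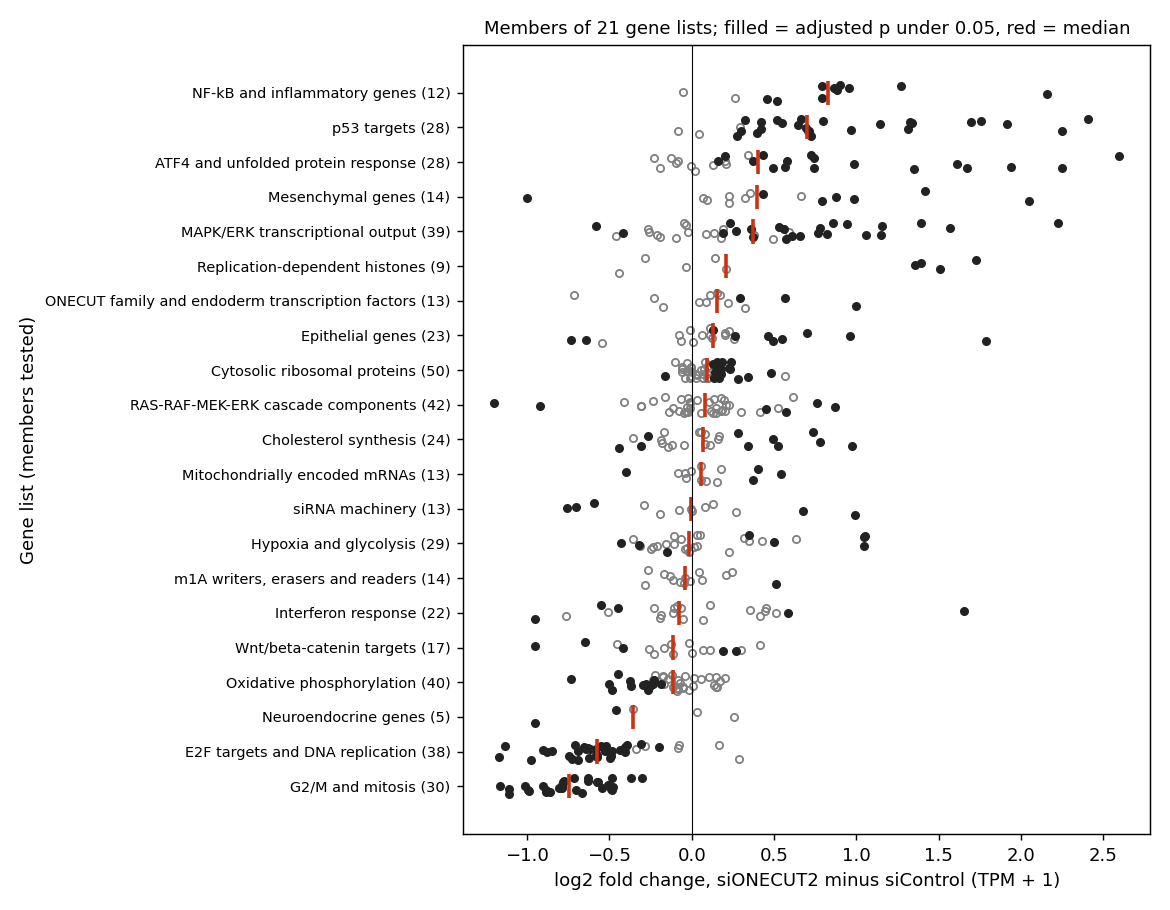
Log2 fold change of siONECUT2 minus siControl for the members of 21 gene lists with at least 5 tested genes; each point is a gene, filled where adjusted p was under 0.05, a red bar marks the median, and the number tested follows each name. The medians run from -0.74 for G2/M and mitosis to 0.83 for NF-kB and inflammatory genes.

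The remaining lists were not called by camera. Wnt/beta-catenin targets had 2 higher and 3 lower members of 17 (2 and 3 adjusted over the list alone; median log2 fold change -0.12, adjusted p = 0.412). DKK1, a secreted Wnt antagonist, fell from 385 ± 17.8 to 199 ± 0.107 TPM, and BMP4 from 454 ± 5.22 to 289 ± 5.76 TPM. Of 13 ONECUT family and endoderm transcription factors, 3 were higher and none lower (3 and 0 adjusted over the list alone; median 0.16, adjusted p = 0.217). The epithelial factor ELF3 was at 50.4 ± 9.26 and 101 ± 5.74 TPM (log2 fold change 1.0, adjusted p = 0.00534), a call lost without siONECUT2 1 (adjusted p = 0.0522). Of 24 cholesterol synthesis genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone; median 0.07, adjusted p = 0.338). INSIG1, a regulator of sterol sensing, rose from 27.7 ± 2.13 to 48.2 ± 0.441 TPM and HMGCS1, a synthase at the head of the pathway, from 83.7 ± 8.11 to 140 ± 5.08 TPM. Of 29 hypoxia and glycolysis genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone; median -0.02 and mean 0.11, which differ in sign; adjusted p = 0.821). The glucose transporter gene SLC2A1 rose from 54.1 ± 1.32 to 113 ± 10.7 TPM, and TPI1, a glycolytic enzyme gene, fell from 911 ± 33.4 to 676 ± 0.688 TPM. Of 14 writers, erasers and readers of m1A, HSD17B10 alone passed the test (1 and 0 adjusted over the list alone; median -0.04, adjusted p = 0.945), rising from 126 ± 5.51 to 181 ± 3.51 TPM. HSD17B10 encodes a subunit of mitochondrial RNase P that also takes part in mitochondrial tRNA methylation. The reader YTHDF1 was at 46.1 ± 3.31 and 38.2 ± 0.857 TPM (adjusted p = 0.0606), and passed as lower with a mean of at least 5 TPM (0.0460), with median-of-ratios scaling (0.0442) and after the GC and length correction (0.0186). YTHDF3 was at 46.5 ± 0.576 and 53.8 ± 2.27 TPM (adjusted p = 0.0765), and passed as higher after that correction (0.0176). Of 5 tested neuroendocrine genes, 2 fell and none rose (2 and 0 adjusted over the list alone; median -0.36, adjusted p = 0.305), STMN1 among them at 636 ± 33.9 and 462 ± 18.5 TPM. Of 13 genes of the siRNA machinery, 2 were higher and 3 lower (2 and 3 adjusted over the list alone; median -0.01, adjusted p = 0.821). TARBP2, a partner of DICER1, was at 44.0 ± 3.36 and 25.7 ± 3.20 TPM (log2 fold change -0.76, adjusted p = 0.00776), a call lost without siControl 2 (adjusted p = 0.0666).

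Lists of other cell types had too few expressed members for a test. No immune marker of 18 reached a mean of 1 TPM. Of 17 fibroblast and endothelial markers, COL1A1 rose from 12.1 ± 0.568 to 25.3 ± 3.00 TPM and ENG was at 1.06 ± 0.474 and 1.15 ± 0.0138 TPM (1 and 0 adjusted over the list alone). Of 12 blood and liver markers, HBA2 was at 3.06 ± 1.14 and 0.618 ± 0.874 TPM (adjusted p = 0.0673) and SERPINA1 at 1.10 ± 0.455 and 1.0 ± 0.638 TPM (0 higher and 1 lower adjusted over the list alone). HBA2 passed as lower after the GC and length correction and without siONECUT2 1 (adjusted p = 0.0302 and 0.0450). Of 30 intestinal differentiation genes, CA2, carbonic anhydrase II, was at 47.3 ± 1.01 and 38.9 ± 0.832 TPM (adjusted p = 0.0350), and DPP4, a brush border peptidase gene, at 21.8 ± 1.11 and 17.7 ± 0.0534 TPM (adjusted p = 0.0646; 0 higher and 2 lower adjusted over the list alone). The CA2 call was lost without any 1 of the 4 libraries (adjusted p from 0.102 to 0.147) and after the GC and length correction (0.146), without the expression filter (0.0588), without the variance trend (0.0837) or with quantile normalization (0.050). Of the 21 lists tested, camera called 10 with a preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.212. The rotation test fry asks whether a list's genes move one way without comparing them with other genes. It called 11 lists, namely those 10 and the histones (adjusted p = 0.0288), and called all 21 for change in either direction. Of all tested genes 25.5% were called, and the latter test passed even the m1A list with 1 of 14 genes called. It therefore singles out no list.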

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

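The correction for GC content and length was chosen after seeing the data. All other alternatives were fixed beforehand.

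The counts of 1610 higher and 1830 lower genes stayed within 1.5 times except in the following. They were 749 and 968 with no expression filter, where 24264 genes were tested, and 1044 and 1186 for eBayes without trend. With adjusted p under 0.01 they were 553 and 772, and with a minimum of 2-fold 190 and 178, as stricter thresholds give. With 1 library left out, which leaves fewer residual degrees of freedom, they ranged from 477 to 625 and from 574 to 795. Of the 3440 calls, between 1049 and 1324 were shared with each of these fits, and none changed sign. Under quantile normalization 2 of 3205 shared calls changed sign. The replicate numbers share only a number, since the differences between replicates 1 and 2 correlated by 0.0132 between the groups. With the replicate block, 1387 and 1640 genes were called, and the ONECUT2 log2 fold change of -0.72 had an adjusted p of 0.115. Among the genes reported, HBA2 was called (adjusted p 0.0257) and CA2 was not (0.0578).

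The ONECUT2 log2 fold change passed the threshold at -0.72 for eBayes without trend (adjusted p 0.0250) and at -0.73 after the GC and length correction (adjusted p 0.0249). It was -0.95 with a pseudocount of 0.5 TPM and -1.30 with 0.1 TPM. Its adjusted p ranged from 0.0249 to 0.230 over all alternatives. The cause was not tested. ONECUT2 gave no value with a mean of at least 5 TPM. The TRMT61A log2 fold change was positive and not called in each alternative.

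The list call of oxidative phosphorylation was lost with quantile normalization (adjusted p 0.263) and after the GC and length correction (adjusted p 0.10). The cause was not tested. With an estimated correlation, where camera uses the 2 residual degrees of freedom, no list was called. The estimate was under the preset 0.01 for MAPK/ERK output (-0.0148), NF-kB (-0.0538) and epithelial genes (-0.00342). It was above 0.01 for the other lists called at the preset value. The adjusted p was 0.212 for MAPK/ERK output, G2/M and p53 targets, 0.216 for E2F targets, epithelial genes, NF-kB, ATF4 and unfolded protein response and ribosomal proteins, 0.283 for mesenchymal genes and 0.282 for oxidative phosphorylation. With 1 library left out, the adjusted p of mitochondrially encoded mRNAs ranged from 0.00127 (without siControl 1) to 0.840 (without siControl 2), and that of histones from 0.0143 (without siControl 1) to 0.119 (without siControl 2). The other lists kept their direction of call and side of the threshold in the other alternatives run. Mitochondrially encoded mRNAs gave no value when those genes were left out or in the GC and length correction.

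Of 1729 values of 117 named genes under alternatives, 1580 kept direction and side of the threshold, 130 lost their call, 19 gained one and 0 reversed, while 7 uncalled values changed sign. Genes under 5 TPM, without an annotated 3' UTR or mitochondrially encoded gave no value in the alternative concerned. Of 97 called named genes, 64 were called with any 1 library left out, 22 in some of those fits and 11 in none. The unknown depth limits what can be said of low genes such as ONECUT2, and 2 libraries per group limit what small changes can be called.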

Other observations

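In this part the tests chosen after the results were seen were those of 6 additional gene lists, the genes named in them, the search for heptamers, the rearrangements of GAAATCA, the comparisons of single siONECUT2 libraries and of siControl 1 with 2, and that of seed effects acting through other genes. The microRNA test was written before its 16 sites were looked at, but after the ranking of heptamers.

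Most chaperone genes listed for the cytosol and mitochondria, and some genes of ribosome assembly, were lower in the siONECUT2 libraries. Of 20 cytosolic and mitochondrial chaperone genes, 17 fell and none rose (median log2 fold change -0.34, camera adjusted p = 6.06e-10 over 6 lists; adjusted p = 0.335 with an estimated correlation). HSP90AA1, an inducible HSP90 gene, fell from 1931 ± 92.7 to 1169 ± 34.5 TPM and HSPA8, the constitutive HSP70 gene, from 1676 ± 76.5 to 1149 ± 35.8 TPM (SD, n = 2 libraries per group). Of 35 ribosome biogenesis genes, 15 fell and none rose (median -0.12, adjusted p = 0.000114; adjusted p = 0.335 with an estimated correlation), although with quantile normalization 11 fell and 1 rose. NOP56, a core protein of box C/D small nucleolar RNPs, fell from 542 ± 4.02 to 222 ± 6.11 TPM, and NPM1, nucleophosmin, from 2602 ± 71.6 to 1443 ± 8.01 TPM. Lists of 20 aminoacyl-tRNA synthetases and 30 proteasome genes were not called (adjusted p = 0.15 and 0.334), with 3 higher and 6 lower genes in each. The proteasome counts were 0 higher and 6 lower with median-of-ratios scaling and 6 higher and 4 lower with quantile normalization, and the synthetase counts 3 and 4 and 3 and 3.

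Most AP-1 genes and many NRF2 targets were higher, although neither list was called with an estimated correlation. Of 16 NRF2 targets, 10 rose and 3 fell (median log2 fold change 0.29, adjusted p = 0.000295; adjusted p = 0.335 with an estimated correlation). HMOX1, heme oxygenase, rose from 22.4 ± 1.65 to 86.0 ± 3.00 TPM. The ferritin genes moved apart, with FTH1 rising from 2988 ± 36.1 to 4879 ± 144 TPM and FTL falling from 1638 ± 47.0 to 895 ± 8.86 TPM. Overlapping genes and pseudogenes were not looked for in FTH1, FTL, HMOX1, HSP90AA1, HSPA8, NOP56 and NPM1, so their levels are uncertain. Of 12 AP-1 family genes, 10 rose and none fell (median 0.59, adjusted p = 2.14e-06; adjusted p = 0.303 with an estimated correlation), and 6 of the 12 were also in the lists described before. The mitochondrial ribosomal RNA MT-RNR2 was listed at 3124 ± 50.6 and 8574 ± 524 TPM and MT-RNR1 at 812 ± 9.84 and 1381 ± 9.13 TPM (log2 fold changes 1.46 and 0.77, adjusted p = 0.000451 and 0.000476). How evenly poly(A) selection captured these ribosomal RNAs in each library is unknown, so their levels are uncertain.

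Genes with the heptamer GAAATCA in the 3' UTR (1636 of 11654 searched) were on average lower in the siONECUT2 libraries, with a z score of -12.6, the lowest of 15643 heptamers, followed by ATGGAAA with -9.43, where 200 random gene orders reached -5.06. GAAATCA was picked as the lowest, so base composition was judged by its 209 rearrangements as a set. It is argued against by their median z score of -0.492 (SD 1.08), where the same bases would give all of them values near that of GAAATCA. A difference carried by 1 library is argued against by z scores of -11.5 and -12.6 in siONECUT2 1 and 2 against the controls, and of 0.321 for siControl 1 minus 2. The next lowest words, AATGGAA (z score -8.66), AAATGGA (-6.98) and AAATCAA (-6.68), overlap ATGGAAA or GAAATCA. Genes with GAAATCA or ATGGAAA in the coding sequence were lower too (z scores -8.05 and -5.52). Pairing of siRNA seeds with 3' UTRs and a loss of ONECUT2 cannot be told apart here. Genes with both heptamers lay below genes with 1 of them by a mean of -0.0689 on the log2 scale (SE 0.02), but both heptamers were picked for their low genes, so this difference supports neither. Of 1740 lower genes searched, 38.3% carried either heptamer in the 3' UTR, against 27.5% of the other genes, so most lower genes had neither there. The siRNA sequences are not given in the sources used here, so the heptamers were not compared with them, and seed pairing stays an untested hypothesis.

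Genes with 3' UTR sites of common microRNA families were on average higher in the siONECUT2 libraries. The median z score of 16 family sites not looked at before was 1.93, with 15 of 16 above 0, and the highest z score of all heptamers was 6.39 for the miR-29 site. The GC count of the heptamers themselves is argued against by 10000 random sets of 16 heptamers with the same GC counts (median -0.07). Of these sets, 100 percent had a lower median than the family sites. The sets were not matched for the 3' UTRs that carry the words, beyond the adjustment of the z scores. That adjustment lowered some z scores strongly, from 10.5 to 3.32 for miR-24 and from 8.60 to 3.84 for the miR-15 family. Others it did not lower, such as that of miR-21 (1.93 before and 2.24 after). The random sets were scored after the same adjustment, so 3' UTR composition that it failed to remove stays open. Random words were drawn singly, whereas some family sites overlap (TGCTGCT and ATGCTGC), so the share of 100 percent is not an exact p-value. Sites of families looked at before, such as miR-29, let-7 and miR-19, were among the highest heptamers. The miR-17 site GCACTTT, 1 of the 16, overlaps CACTTTA, another of the highest (z score 4.97). The 16 sites are therefore not fully separate from that ranking. Less repression by endogenous microRNAs may explain the pattern, as a hypothesis. Whether such sites are frequent in short-lived and stress-induced mRNAs was not tested, which leaves that explanation and a loss of ONECUT2 open.

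The rise of p53 targets and the fall of cell cycle genes were set against 3 technical explanations. Direct pairing at GAAATCA or ATGGAAA is argued against only for the 27 of 68 cell cycle members with neither heptamer. Their median log2 fold change was -0.57 (upper quartile -0.44) against -0.63 for all. By list, the median was -0.56 with neither and -0.78 with either for G2/M, and -0.58 and -0.55 for E2F targets. Overlapping words such as AATGGAA (z score -8.66 in 3' UTRs) were not excluded, so pairing through these stays open. Under 3 other scalings the largest adjusted p of the p53, E2F and G2/M lists was 7.32e-15 by camera with a preset correlation. At an estimated correlation, without rescaling, camera gave adjusted p = 0.212, 0.216 and 0.212. Camera compares a list with other genes, so a factor shared by a whole library could hardly change it. The scalings moved the median log2 fold change of all tested genes only to between -0.00698 and 0.0121. No conclusion on scaling is drawn from this. Seed effects acting through other genes and a loss of ONECUT2 cannot be told apart for these lists, since siONECUT2 1 and 2 differed little in the GAAATCA signal (z score of their difference 1.71) and no second siRNA or rescue was analysed here. Both may contribute, and neither was tested alone.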
